A study of Mus musculus with 23 samples.

How the data were processed

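RNA from 18 cell samples and 5 mouse tissues was measured on 23 arrays of the Agilent whole mouse genome 4x44K design, 1 array per sample, with 1 dye (Cy3) per array. Per the labels, the cells were embryonic fibroblasts from the dorsal skin (dorsal MEF) and the limb skin (limb MEF) of E13.5 embryos, dermal fibroblasts (MDF) of ear-base skin taken at 12 weeks of age, and the iLung cells made from each of these 3 sources by retroviral transduction of transcription factors. The labels do not name the factors. Per the labels, the fibroblasts were kept in medium with 12% FBS, and the iLung cells in the same medium for 7 days and then in another medium with 0.2% FBS for 10 days, so that transduction and medium cannot be told apart in any comparison of iLung cells with fibroblasts. Each of the 6 cell groups had 3 arrays, and each tissue (E11.5 lung and, at 8 weeks, lung, trachea, esophagus and thyroid) had 1. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

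Each deposited scanner file held the processed signal of every spot as an intensity, already background-subtracted and detrended within its array, per the file headers and columns of Agilent Feature Extraction. The file headers name version 11.5.1.1 of that software, whereas the submitters' processing notes name version 10.5. Labelling started from 600 ng of RNA, per the labels. The deposited value table of the series held log2 values whose making the labels do not describe. Set against the scanner files, differences between arrays in that table had a slope of 1 and a correlation of 1 with differences in log2 processed signal, after an offset per array. The offset minus the log2 of the array's 75th percentile had an SD of 0.0015 over the arrays. Every probe of the table had a median of 0 over the 23 arrays, and the median of its columns ran from -0.35 (adult lung) to 0.25 (MDF replicate 3). The table was used only as an alternative.

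Each array had 45018 spots, 43379 of them not controls, for 41174 probes. Control spots were left out, spots of the same probe were averaged as log2 values, and 231 probes that the scanner software marked as outliers on any array were left out, which kept 40943. No spot was saturated. Values were log2 of the processed signal minus the array's 75th percentile. Symbols came from a RefSeq table of the assembly GRCm38.p6, matched through unversioned accessions, which gave a symbol to 27816 probes (18952 genes) and none to 13358. A probe was tested when it was well above background on all 3 arrays of at least 1 of the 6 cell groups, which held for 30298 probes. A gene (a symbol or, with none, an accession) was represented by its tested probe with the highest mean over the 18 cell arrays, which gave 22789 genes, 15773 of them with a symbol. Other probes disagreed in part: 1112 of the genes called in the averaged comparison had 1424 further tested probes, of which 906 were called the same way, 507 were not called and 11 were called the opposite way.

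The 18 cell arrays were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group, with lmFit and eBayes, and no block. The fit left 12 residual degrees of freedom, with a prior of 2.62 from eBayes. A gene was called when its Benjamini-Hochberg adjusted p over the 22789 genes was under 0.05 and its change at least 2-fold. The contrasts were iLung cells against fibroblasts within each source, their average over the 3 sources, the differences of these changes between sources, and the differences between sources among fibroblasts and among iLung cells. Every adjusted p in the text comes from this fit unless another test is named. Figures were drawn with matplotlib 3.10.9, and files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

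A gene not well above background on any array of a group has only a bound there. For such a gene, the fold is given as at least N-fold: the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Averaged changes of genes that were well above background on only some arrays of a side rest in part on signal near background, and the numbers of arrays are given where a side had 4 or fewer of 9.

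Before the data were examined, 37 gene lists were written (lung epithelial types, lung and foregut transcription factors, lung mesenchyme, epithelial and mesenchymal genes, matrix, contractile, basement membrane, cell cycle, p53, senescence, cholesterol synthesis, immediate early, interferon, inflammatory, unfolded protein response, limb and trunk Hox, dorsal dermis, and markers of other cell types and organs), together with the tests, the alternatives and the rule for the genes named. Each list was tested with camera at its preset correlation of 0.01 in 4 comparisons (148 tests adjusted together), and again with the correlation estimated from the data. A list of abundant macrophage transcripts and a list of differentiated epidermis were written after the values of the fixed lists had been seen and before their own were. Tests of the 37 lists between sources, 333 in all, were also added after the data had been seen. Tissue lists held the genes at least 4-fold higher on 1 tissue array than on each of the others (or, for lung, than on the other adult tissues or at the other age), and were tested in the same way (32 tests). These lists were chosen on the arrays of this series, with 1 array per tissue.

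The named genes have a symbol and are not numbered gene models. They are the 10 largest rises and the 10 largest falls among genes called alike in all 3 sources and well above background on all 18 arrays; up to 6 per direction that were well above background on all 9 arrays of one side and none of the other; 3 per direction and source that were called in that source alone and differed from both other sources; up to 4 called members per list; 6 per direction between fibroblast sources and 3 per direction between iLung cells; 4 per tissue; and 11 lung and epithelial genes whether called or not. Some genes that the rule picks are not reported here. Any gene named outside this rule was chosen after its values were seen.

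Similarity to each tissue was Spearman's correlation across the 29055 genes well above background on at least 1 of the 23 arrays. Its difference between the 9 iLung and the 9 fibroblast arrays was tested with an exact two-sided permutation test within source, whose smallest p is 0.00025, adjusted over the 5 tissues.

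Precision is limited by the number of arrays. In a copy of the comparison of iLung cells with limb MEF made of simulated values for 22789 genes, the fit called 16% of 50 genes changed 2-fold, 66% of those changed 4-fold, 82% at 8-fold and 100% at 16-fold, with 4 unchanged genes called. The copy changed few genes and had independent noise without an effect of the slide, whereas 5148 genes were called in the real comparison. Its rates are therefore not those of the data. A change of exactly 2-fold also lies on the minimum fold of a call, which limits that rate by itself. The alternatives tried were quantile normalization; normexp background correction with an offset of 50; no filter and a filter on all 18 arrays; the mean of a gene's probes; no minimum fold; an intensity trend with robust variances; the deposited value table; a fit of only the groups compared; the replicate number and the slide as a block; leaving out each array; camera with an estimated correlation and fry; tissue lists at 2-fold and 8-fold; and Pearson's correlation, the 2000 most variable genes or genes well above background on all 23 arrays for similarity. Scan day as a block, slide as a random block and the second scan day only were added after the data had been seen. The files lack the mean spot signal, so normexp used the median spot signal and the median local background. Tissue arrays, with 1 each, entered no test across genes.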

Results

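Gene expression was measured in induced lung progenitor (iLung) cells, in the 3 kinds of mouse fibroblast they were made from, and in 5 tissues, with 1 array per sample. The 18 cell arrays formed 6 groups of 3: dorsal MEF and limb MEF (fibroblasts from the dorsal and the limb skin of E13.5 embryos), MDF (fibroblasts of ear-base skin, taken at 12 weeks of age), and the iLung cells made from each. The tissues were the lung at E11.5 and the lung, trachea, esophagus and thyroid at 8 weeks, with 1 array each and so no replicates. On the cell arrays, 59.2% (iLung cells from dorsal MEF, replicate 2) to 79.1% (limb MEF, replicate 1) of 41174 probes were well above background, and on the tissue arrays 64.0% (esophagus) to 79.4% (adult lung). The 75th percentile of the processed signal, by which each array was scaled, ran from 550 to 1447 on the cell arrays and from 429 to 1891 on the tissue arrays. Within a group, Pearson's correlation across probes between replicates was 0.957 to 0.992, where probes are not independent replicates.

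The arrays of iLung cells and fibroblasts separated along the first principal component, which held 41.7% of the variance, with fibroblast arrays from -100.3 to -84.4 and iLung arrays from 69.6 to 123. The second component held 18.5%, and along it MDF and the iLung cells from MDF (-110.4 to -59.6) lay apart from the dorsal MEF and their iLung cells (38.2 to 92.9). Replicate 1 of each cell group was scanned on the first day and replicates 2 and 3 on the second, each pair on 1 slide together with the iLung cells of the same source. Comparisons within a source are therefore crossed with slide and scan day, whereas slide and source cannot be told apart.

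**Figure D1:**
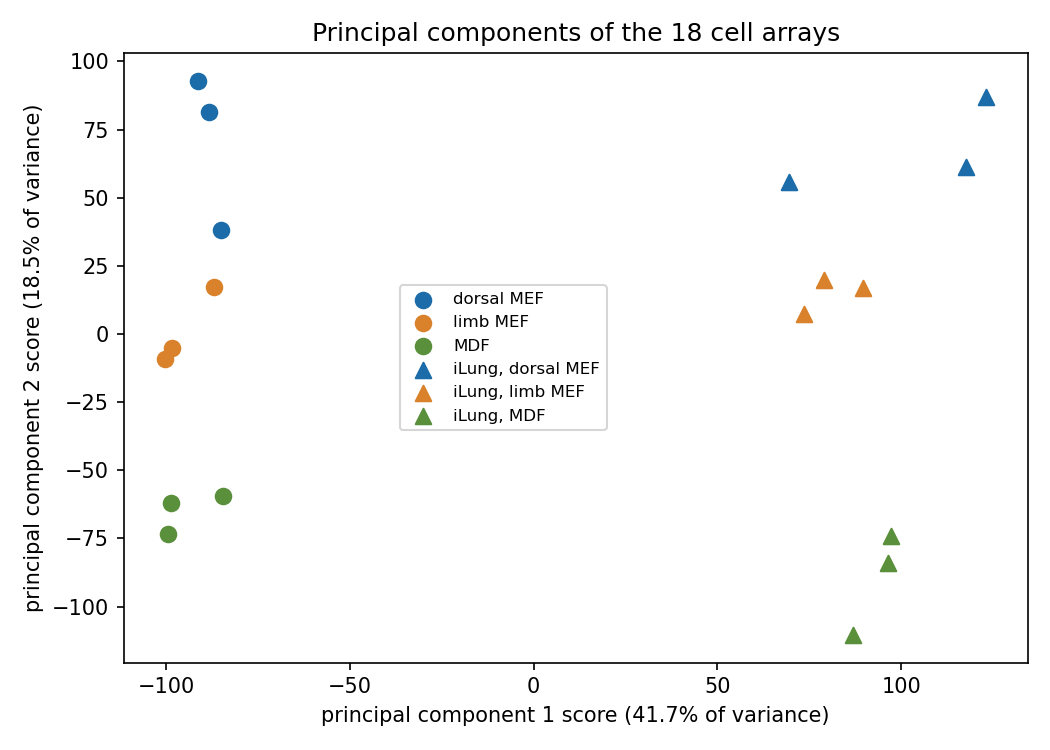
Principal components of the 18 cell arrays, from log2 signals scaled by each array's 75th percentile, with the first component on the x axis, the second on the y axis, circles for fibroblasts, triangles for iLung cells and a colour per source. The 9 fibroblast arrays lie between -100.3 and -84.4 on the first component, and the 9 iLung arrays between 69.6 and 123.

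The comparison of iLung cells with the fibroblasts they were made from, averaged over the 3 sources (n = 9 and 9 arrays), asks which genes differ after transduction and the change of medium. Krt8, a keratin of simple epithelia, rose by 11.52 ± 0.28 (log2, SE) and was well above background on all 9 iLung arrays and 6 of 9 fibroblast arrays. Its partner Krt18 rose by 10.11 ± 0.25 (on 9 and 7 arrays). Cdh1, the adhesion protein of epithelial junctions, was well above background on all 9 iLung arrays and on none of the fibroblast arrays, and was at least 165-fold higher (adjusted p = 9.11e-13). In the same on-and-off manner, Gdf2, a bone morphogenetic protein, was at least 117-fold higher, Foxa2, a transcription factor of the foregut endoderm, at least 52.3-fold, Jag2, a Notch ligand, at least 49.6-fold, the aldehyde dehydrogenase Aldh3a1 at least 27.8-fold, and Nkx2-1, a transcription factor of lung and thyroid, at least 20.5-fold. Sftpc, the surfactant protein of alveolar type 2 cells, rose by 7.88 ± 0.31 and was well above background on 9 iLung arrays and 1 fibroblast array. Epcam, an epithelial surface protein, rose by 4.80 ± 0.47 (on 9 arrays and 1). Gata6, a transcription factor of the endoderm, rose by 1.89 ± 0.28 on its brightest probe. Its other tested probes disagreed, at 3.82 (called) and 0.17 (not called). Sox2 rose by 1.52 ± 0.41 (on 7 and 5 arrays) and Foxj1, which drives ciliogenesis, by 3.01 ± 0.30 (on 8 and 1), and both calls were lost with normexp background correction (0.19 and 0.64). By source, Sox2 was at least 5.14-fold higher against dorsal MEF and did not pass against limb MEF (-0.11) or MDF (1.03). Sox9 (0.39 ± 0.23, adjusted p = 0.165) and Scgb1a1, the secretory protein of club cells (0.71 ± 0.41, adjusted p = 0.155), did not pass, and Foxa1 was not tested, being well above background on 1 of 18 arrays. The labels do not name the transduced factors, and whether the signal of a transcription factor came from the cells' own gene or from a vector was not tested.

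Among genes called alike in all 3 sources and measured on all 18 arrays, the largest rises were those of the basal cell keratins Krt5 (7.41 ± 0.56) and Krt14 (7.30 ± 0.58), of Lsr (7.16 ± 0.23), a protein of tricellular junctions, and of the secreted chaperone Clu (6.96 ± 0.29). They were followed by Cmtm8 (6.16 ± 0.32), the planar polarity cadherin Celsr1 (6.05 ± 0.27), the gastric trefoil peptide Tff1 (5.98 ± 0.55), the immediate early gene Fos (5.29 ± 0.34), the zinc importer Slc39a4 (5.21 ± 0.26) and Cracdl (5.18 ± 0.28). The largest falls were those of Il1rl1, the receptor of interleukin 33 (-6.00 ± 0.26), the kinesin Kif1a (-4.92 ± 0.14) and the BMP antagonist Grem1 (-4.66 ± 0.32). Ptprn (-4.53 ± 0.21), the urea cycle enzyme Ass1 (-4.45 ± 0.18), the chromatin protein Hmga2 (-4.32 ± 0.31), the fibroblast surface protein Thy1 (-4.24 ± 0.28), the prostaglandin E synthase Ptges (-4.07 ± 0.20) and Loxl3, a lysyl oxidase (-3.95 ± 0.22), also fell. Dok5 was well above background on all 9 fibroblast arrays and no iLung array and was at least 6.69-fold lower. Asic3 (at least 4.83-fold lower), Scg5 (at least 3.83-fold) and H2bc6 (at least 2.84-fold) had the same pattern, and their calls were lost with normexp.

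In the averaged comparison 2491 genes were called higher and 3656 lower of 22789 tested. Of these 6147 genes, 6132 had the same sign on both scan days. The median change of all genes was -0.09, and it was -0.03 with quantile normalization. The numbers higher and lower were 1218 and 1719 with only the genes well above background on all 18 arrays, and 1184 and 1549 with normexp. Genes without a symbol made up 59.3% of the lower calls and 19.6% of the higher ones.

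**Figure D2:**
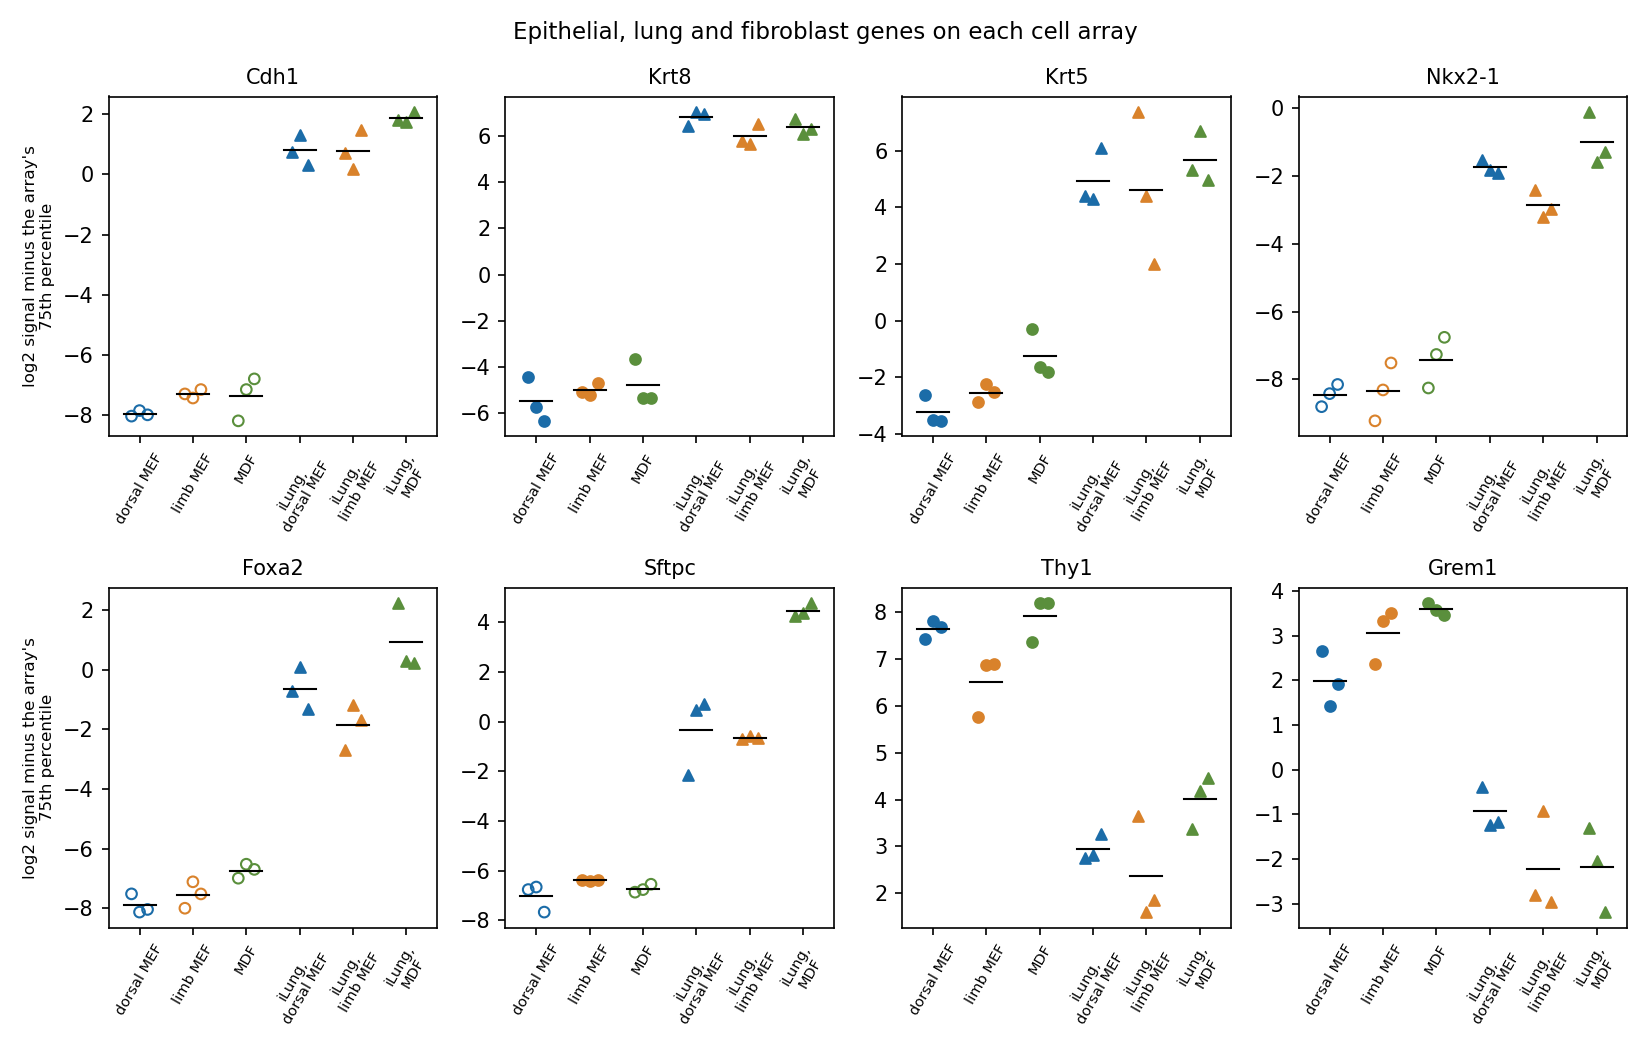
Signal of 8 genes on each of the 18 cell arrays, as log2 minus the array's 75th percentile on the y axis, by group on the x axis, with circles for fibroblasts, triangles for iLung cells, a bar for the mean of 3 arrays and open symbols for groups in which none of the 3 arrays was well above background. Krt8 has group means of 6.0 to 6.82 in iLung cells and -5.51 to -4.80 in fibroblasts, and Thy1 2.37 to 4.01 and 6.50 to 7.91.

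The genes of lung epithelial cells were split by cell type. Of 13 measured club and secretory cell genes, 10 rose and none fell (camera adjusted p = 7.18e-06, and adjusted p = 0.0629 with an estimated correlation). They included the trefoil peptide Tff2 (7.24 ± 0.55, on 9 iLung arrays and 1 fibroblast array), the antibacterial lectin Reg3g (5.92 ± 0.46, on 8 and 3), the mucin Muc5b (3.63 ± 0.48) and Aldh1a1 (3.33 ± 0.27). Of 10 airway basal cell genes, 7 rose and 1 fell (camera adjusted p = 0.000204, and adjusted p = 0.223 with an estimated correlation). Besides Krt5 and Krt14, the rises included Krt15 (7.17 ± 0.55) and Trp63, the transcription factor of basal cells (6.53 ± 0.47). Of 11 alveolar type 2 genes, 6 rose and none fell (camera adjusted p = 0.00145, and adjusted p = 0.0711 with an estimated correlation). Sftpc was joined by the protease Napsa (4.01 ± 0.47), Chil1 (3.62 ± 0.48) and Cxcl15 (3.46 ± 0.33, on 9 and 4). The median change of this list was 1.41, and 0.64 with the member that has only a bound set to it. Of 28 lung and foregut transcription factors, 10 rose and 3 fell (camera adjusted p = 0.00343, and adjusted p = 0.0910 with an estimated correlation). Hhex (4.53 ± 0.30) and Grhl1 (3.26 ± 0.20) rose besides Foxa2 and Nkx2-1. The calls of the last 2 lists were lost among genes well above background on all 18 arrays, and that of the transcription factors also with normexp. Of 12 alveolar type 1 genes, 5 rose and 1 fell (camera adjusted p = 0.138). The rises included Akap5 (4.26 ± 0.29), Ager (4.09 ± 0.34) and the claudin Cldn18 (4.01 ± 0.62, on 7 iLung arrays and 1 fibroblast array). Of 17 ciliated cell genes, 4 rose, 3 fell and 10 did not pass (camera adjusted p = 0.267). Foxj1, Tekt1 (1.76 ± 0.32, on 9 and 1) and Rfx2 (1.61 ± 0.19) rose and Rsph1 fell (-1.77 ± 0.19), and all of these calls were lost with normexp. Of 14 lung mesenchyme genes, 3 rose and 4 fell (camera adjusted p = 0.643). The growth factors Fgf10 (-3.51 ± 0.26) and Wnt2 (-2.59 ± 0.19) fell, against rises of Lmcd1 (2.06 ± 0.24) and Mfap4 (1.87 ± 0.43).

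Of 27 epithelial junction and keratin genes, 23 rose and none fell (camera adjusted p = 1.64e-11, and adjusted p = 0.0629 with an estimated correlation). Their median change was 2.50, or 2.32 with the 5 members that have only a bound set to it, and Krt23 was at least 104-fold higher. Of 14 mesenchymal transcription factor and adhesion genes, none rose and 8 fell (camera adjusted p = 9.58e-05, and adjusted p = 0.0629 with an estimated correlation). Those with the largest falls were S100a4 (-3.60 ± 0.24), Snai1 (-3.29 ± 0.25), Twist2 (-2.55 ± 0.27) and Foxc2 (-2.15 ± 0.23). Of 14 smooth muscle and contractile genes, 1 rose and 8 fell (camera adjusted p = 0.0204, and adjusted p = 0.598 with an estimated correlation). Cnn1 (-3.92 ± 0.31), Lmod1 (-2.80 ± 0.24), Tpm2 (-2.59 ± 0.28) and Myh11 (-2.25 ± 0.38) fell most. The list's call was lost without replicate 1 of the iLung cells from dorsal MEF (median -1.11). Of 25 fibroblast matrix genes, 6 rose and 12 fell (camera adjusted p = 0.0588). Thy1 fell, whereas elastin (Eln, 2.94 ± 0.35) and the proteoglycans Ogn (2.78 ± 0.34) and Lum (2.59 ± 0.26) rose. Of 14 basement membrane genes, 2 rose and 5 fell (camera adjusted p = 0.427). The laminins Lamb3 (3.52 ± 0.39, on 9 and 4 arrays) and Lama5 (2.06 ± 0.19) rose, against falls of Lama4 (-1.93 ± 0.15) and the proteoglycan Hspg2 (-1.44 ± 0.19).

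Among lists of cell processes, 10 of 24 cell cycle genes rose and none fell (camera adjusted p = 0.000172, and adjusted p = 0.598 with an estimated correlation). The replication genes Mcm7 (1.56 ± 0.18), Mcm6 (1.46 ± 0.23) and Cdc6 (1.45 ± 0.23) rose most. Of 18 immediate early genes of the serum response, 12 rose and 1 fell (camera adjusted p = 0.000219, and adjusted p = 0.533 with an estimated correlation). Besides Fos, Atf3 (3.57 ± 0.26) and Fosb (3.22 ± 0.47) rose, and Fosl1 fell (-3.36 ± 0.26). Of 23 cholesterol synthesis genes, none rose and 6 fell (camera adjusted p = 0.00146, and adjusted p = 0.598 with an estimated correlation). They included Sc5d (-1.43 ± 0.20) and Msmo1 (-1.35 ± 0.19). Of 21 interferon response genes, 1 rose and 7 fell (camera adjusted p = 0.340). Stat2 fell (-2.49 ± 0.24), and the chemokine Cxcl10 rose (2.19 ± 0.35). Of 17 inflammatory cytokine and acute phase genes, 8 rose and 6 fell (camera adjusted p = 0.279). Il33 (4.54 ± 0.26) and Cxcl2 (3.36 ± 0.32, on 6 and 2 arrays, a call lost with normexp) rose, and Cxcl5 (-3.78 ± 0.39) and Ccl7 (-2.99 ± 0.29) fell. By source, the list's median was 2.78 (dorsal MEF), 0.05 (limb MEF, 6 rose and 3 fell, camera adjusted p = 0.322) and -0.56 (MDF, 1 rose and 6 fell, camera adjusted p = 0.146). Of 15 p53 targets, 2 rose and 2 fell (camera adjusted p = 0.919, median -0.28 and mean 0.08). Perp, a protein of desmosomes, rose (3.71 ± 0.30), and the kinase inhibitor Cdkn1a fell (-1.12 ± 0.17), a call lost with quantile normalization (-0.96). Of 11 senescence genes, 3 rose and 5 fell (camera adjusted p = 0.568). The proteases Mmp10 (-2.0 ± 0.35) and Mmp3 (-1.62 ± 0.36) fell, and Igfbp5 rose (1.94 ± 0.30). Of 13 genes of the unfolded protein response, none rose and 2 fell (camera adjusted p = 0.146), Ddit3 (-2.64 ± 0.18) and Trib3 (-1.60 ± 0.31).

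Markers of other cell types also moved. All 13 macrophage genes that passed, of 14 measured, rose in the average (camera adjusted p = 1.46e-07, and adjusted p = 0.0711 with an estimated correlation). Against MDF alone, 1 rose and 2 fell (median -0.67). The largest averaged rises were those of Adgre1 (3.15 ± 0.35), Mpeg1 (3.07 ± 0.27), Ptprc (2.81 ± 0.23) and Tyrobp (2.74 ± 0.46). Of 7 mesothelium genes, 6 rose and none fell (camera adjusted p = 9.58e-05, and adjusted p = 0.0608 with an estimated correlation). They included Gpm6a (8.00 ± 0.29, well above background on 9 iLung arrays and 1 fibroblast array), Upk3b (5.20 ± 0.39, on 9 and 3), Bnc1 (4.14 ± 0.27, on 9 and 6) and Upk1b (3.20 ± 0.39, on 7 and 3). Of 13 liver and intestine genes, 8 rose and 1 fell (camera adjusted p = 0.000212, and adjusted p = 0.0711 with an estimated correlation). They included the genes of the plasma proteins Trf (4.90 ± 0.16), Alb (4.69 ± 0.42, well above background on 8 iLung arrays and 1 fibroblast array), Rbp4 (4.38 ± 0.37) and Fgb (4.27 ± 0.28, on 9 and 2). Of 12 chondrocyte genes, 8 rose and none fell (camera adjusted p = 9.20e-05, and adjusted p = 0.0712 with an estimated correlation). The cartilage matrix genes Comp (3.33 ± 0.38) and Matn3 (2.76 ± 0.27) were among them. Of 11 adipocyte genes, 6 rose and none fell (camera adjusted p = 0.00245, and adjusted p = 0.0711 with an estimated correlation). The fatty acid transporter Cd36 rose most (4.04 ± 0.42), and the list's call was lost among genes well above background on all 18 arrays. The remaining lists did not pass. Of 10 stratified esophageal genes, 4 rose and 2 fell (camera adjusted p = 0.287). Krt13 (4.03 ± 0.31) and Krt6a (3.64 ± 0.56) rose, and Crct1 (-4.21 ± 0.45) and Ecm1 (-2.96 ± 0.22) fell. Of 6 stomach and pancreas genes, 2 rose and 1 fell (camera adjusted p = 0.212), with Gkn2 (6.61 ± 0.53, on 9 and 2) and Tff1. Of 5 thyroid genes, 1 rose and 1 fell (camera adjusted p = 0.921), and thyroglobulin (Tg) was the gene that fell (-1.68 ± 0.22). Of 7 keratinocyte genes, 2 rose and none fell (camera adjusted p = 0.374), Krtdap (2.68 ± 0.39, on 9 and 4) and Krt1 (1.30 ± 0.44, on 8 and 4), both lost with normexp. Of 8 neuron genes, 1 rose and 2 fell (camera adjusted p = 0.919, median -0.16 and mean 0.04), with Syt1 (3.23 ± 0.24) and Stmn2 (-1.87 ± 0.32). Of 9 endothelial genes, 2 rose and 2 fell (camera adjusted p = 0.831), with Eng (-1.91 ± 0.12) and Flt1 (-1.88 ± 0.18). Of 14 skeletal muscle genes, 1 rose and 4 fell (camera adjusted p = 0.614), with Des (-3.42 ± 0.30, on 3 and 8, and on no iLung array from dorsal or limb MEF). Of 7 osteoblast genes, 2 rose and 3 fell (camera adjusted p = 0.933), with Dlx5 (1.91 ± 0.16) and the osteopontin gene Spp1 (-1.27 ± 0.26). Of 11 dorsal dermis genes, 2 rose and 2 fell (camera adjusted p = 0.749), with Meox1 (3.27 ± 0.57). Of 21 limb patterning and posterior Hox genes, none rose and 4 fell (camera adjusted p = 0.210), and of 20 anterior and trunk Hox genes, 2 rose and 2 fell (camera adjusted p = 0.749). None of 8 melanocyte and neural crest genes passed (camera adjusted p = 0.791, median -0.06 and mean 0.04).

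Counts adjusted over the list alone were equal to those over all genes tested in each of the 37 lists of the averaged comparison. Camera called 15 of these lists, and 60 of 148 tests over the 4 comparisons. Of the 60, 59 had their median in the called direction on both scan days, the exception being the cell cycle list against limb MEF. With the scan day or the slide as a block, which by the layout of the arrays leaves the medians as they are, 59 were called in each case, but none of them was called with an estimated correlation, where the smallest adjusted p was 0.0608 and 38 of the 148 tests had an unadjusted p under 0.05. With fry, which tests whether a set moves 1 way on balance, 98 of the 148 tests passed.

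**Figure D3:**
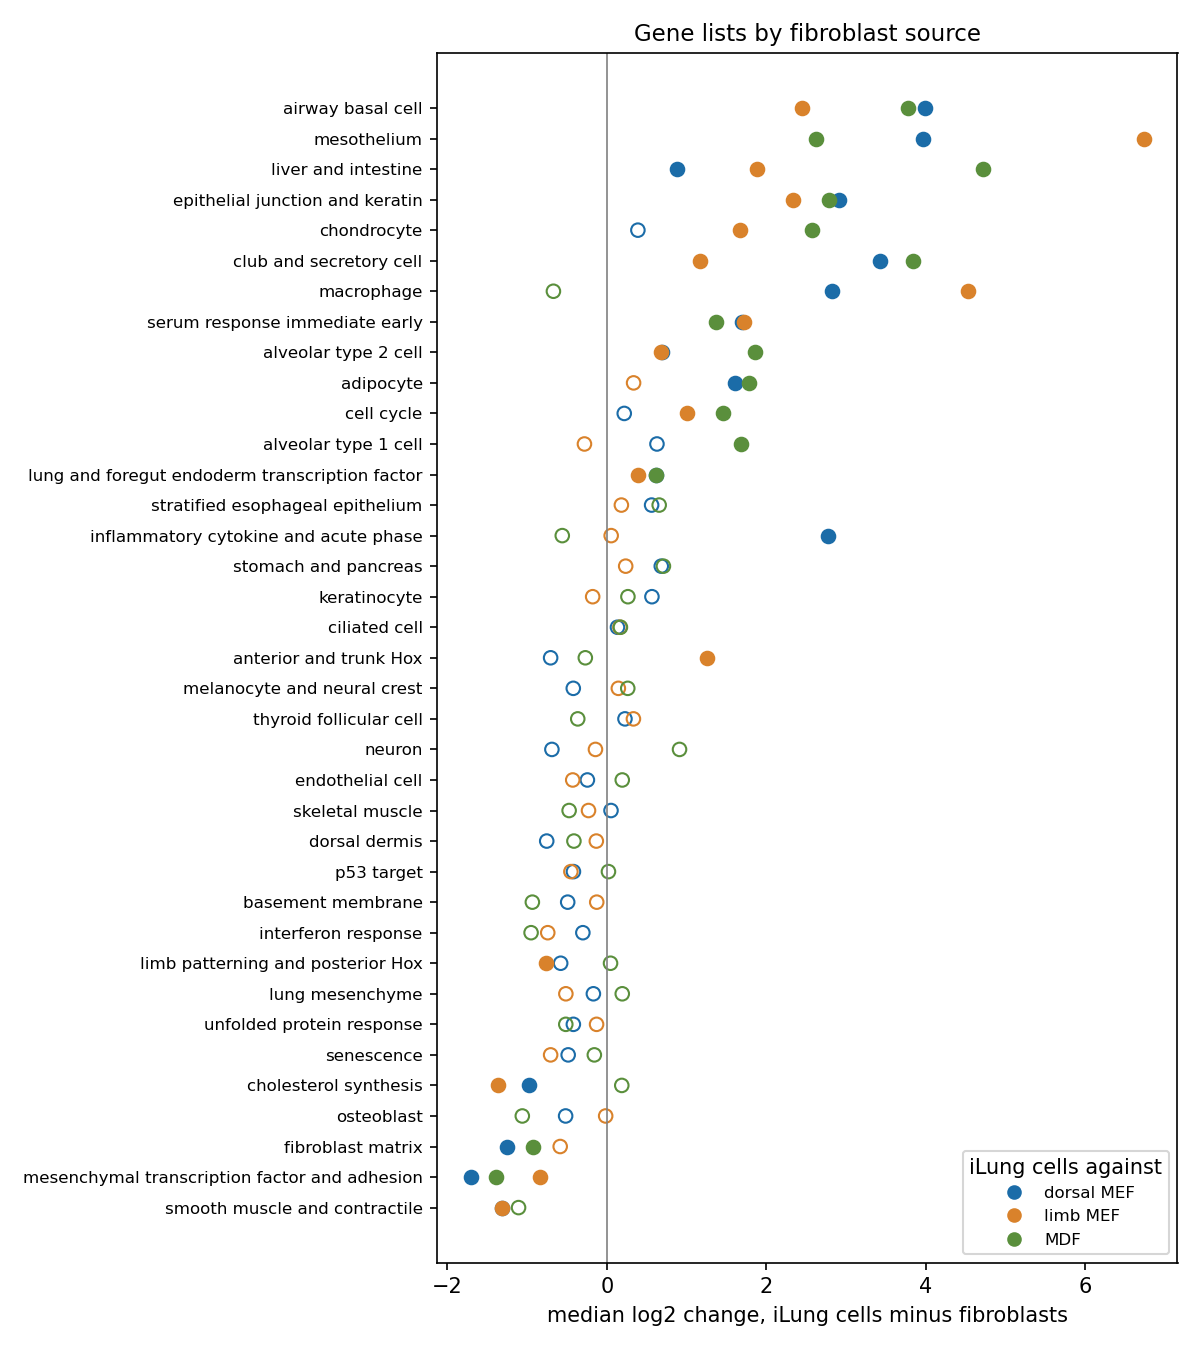
Median log2 change of each of the 37 fixed gene lists (x axis) in iLung cells against dorsal MEF, limb MEF and MDF (colours), with lists ordered by their averaged median, filled circles for a camera adjusted p under 0.05 and open circles for the rest. The macrophage list has medians of 2.82 and 4.53 in the comparisons with dorsal and limb MEF and -0.67 in that with MDF.

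Against dorsal MEF (n = 3 and 3), iLung cells had rises of Krt8 (12.33 ± 0.49), Krt5 (8.16 ± 0.97) and Fos (6.12 ± 0.60), and Sftpc, on all 3 iLung arrays and no fibroblast array, was at least 67.6-fold higher. Cdh1 was at least 155-fold higher, Foxa2 at least 57.2-fold and Nkx2-1 at least 26.6-fold. Of 17 inflammatory genes, 10 rose and 3 fell (10 and 4 adjusted over the list alone), a list called in this comparison (camera adjusted p = 0.000608, and adjusted p = 0.310 with an estimated correlation). The rises included Saa3 (6.32 ± 1.12) and Il33 (5.78 ± 0.45). All 14 macrophage genes rose, by a median of 2.82 (2.94 and 2.92 on the 2 scan days; camera adjusted p = 2.49e-10, and adjusted p = 0.0629 with an estimated correlation). Of 23 cholesterol synthesis genes, 11 fell and none rose (camera adjusted p = 0.000482, and adjusted p = 0.598 with an estimated correlation), with Sc5d (-1.92 ± 0.34). No cell cycle gene passed. In all, 2253 genes were called higher and 3521 lower, and 5600 of these 5774 had the same sign on both scan days. The median change of all genes was -0.19 (-0.07 with quantile normalization). With normexp the counts were 760 and 796, and among genes well above background on all 18 arrays 1299 and 1901.

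Against limb MEF (n = 3 and 3), Krt8 rose by 11.02 ± 0.49, Krt5 by 7.15 ± 0.97 and Sftpc by 5.74 ± 0.54 (on 3 iLung arrays and 1 limb MEF array), while Cdh1 was at least 167-fold higher, Foxa2 at least 27.7-fold and Nkx2-1 at least 13.7-fold. All 14 macrophage genes rose, by a median of 4.53 (4.67 and 4.42 on the 2 scan days; camera adjusted p = 1.33e-14, and adjusted p = 0.0608 with an estimated correlation), with Adgre1 (6.07 ± 0.61) and Ptprc (5.77 ± 0.41). Of 7 mesothelial genes, 5 rose (6 adjusted over the list alone), with Upk3b at least 98.1-fold higher and a list median of 5.51 when the 5 members that have only a bound are set to it (camera adjusted p = 7.56e-06, and adjusted p = 0.0608 with an estimated correlation). Of 20 anterior and trunk Hox genes, which mark positions along the trunk, 7 rose and none fell (camera adjusted p = 0.00224, and adjusted p = 0.191 with an estimated correlation). Of 21 limb patterning and posterior Hox genes, 9 fell and none rose (camera adjusted p = 0.00607, and adjusted p = 0.0629 with an estimated correlation). They included Hoxd13 (-2.85 ± 0.47) and Lhx2 (-2.63 ± 0.58). Of 12 chondrocyte genes, 8 rose and 1 fell (camera adjusted p = 4.16e-05, and adjusted p = 0.0711 with an estimated correlation). Of 23 cholesterol synthesis genes, 19 fell (camera adjusted p = 3.15e-08, and adjusted p = 0.294 with an estimated correlation), with Msmo1 (-2.10 ± 0.32). Of 24 cell cycle genes, 10 rose (11 adjusted over the list alone; camera adjusted p = 0.000366, and adjusted p = 0.598 with an estimated correlation), with a median that turned between the scan days (-0.28 on the first and 1.71 on the second). Among 13 club cell genes 4 rose, a call that rested on replicate 1 of the iLung cells (camera adjusted p = 0.0139, and adjusted p = 0.294 with an estimated correlation), since without that array the list did not pass (median 1.13). In all, 2171 genes were called higher and 2977 lower, and 5053 of these 5148 had the same sign on both scan days. With normexp the counts were 943 and 968, and among genes well above background on all 18 arrays 1260 and 1582.

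Against MDF (n = 3 and 3), Sftpc, on all 3 iLung arrays and no MDF array, was at least 1040-fold higher. Of 6 stomach and pancreas genes, Gkn2 (9.63 ± 0.93, on 3 iLung arrays and 1 MDF array) and Tff1 (9.43 ± 0.96) rose and the list did not pass (camera adjusted p = 0.0544). Of 13 club cell genes, 11 rose (camera adjusted p = 7.20e-08, and adjusted p = 0.0608 with an estimated correlation). Of 12 alveolar type 1 genes, 6 rose and 2 fell (camera adjusted p = 0.00683, and adjusted p = 0.0842 with an estimated correlation), with Ager (6.44 ± 0.59, on 3 iLung arrays and 1 MDF array). Of 24 cell cycle genes, 16 rose and none fell (19 adjusted over the list alone; camera adjusted p = 5.13e-07, and adjusted p = 0.464 with an estimated correlation). Of 13 liver and intestine genes, 8 rose (camera adjusted p = 7.18e-06, and adjusted p = 0.0608 with an estimated correlation). Macrophage genes did not rise as a list: 1 rose, 2 fell and 11 did not pass, with a median of -0.67 (-1.61 and 0.16 on the 2 scan days; camera adjusted p = 0.346). Of 23 cholesterol genes, 3 rose and none fell (camera adjusted p = 0.254). In all, 2338 genes were called higher and 3472 lower, and 5789 of these 5810 had the same sign on both scan days. With normexp about 1.1e+03 genes were called higher and 1388 lower, and among genes well above background on all 18 arrays 1388 were called higher and 2002 lower.

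The 3 comparisons shared 882 genes called higher and 1730 called lower, where independent lists of the same sizes would share 22.0 and 70.1. The comparisons use 1 estimate of each gene's spread, so their calls are not independent, and the numbers for independent lists are only a rough baseline. The comparisons with dorsal and limb MEF shared 1387 higher and 2112 lower calls (214.6 and 460 for independent lists), dorsal MEF and MDF 1247 and 2363 (231.1 and 536.4), and limb MEF and MDF 1256 and 2059 (222.7 and 453.6). Genes called in opposite directions numbered 55, 88 and 123 in these pairs, and Pearson's r of the changes across genes, which are not independent replicates, was 0.768, 0.729 and 0.681. The shared counts were 453 and 852 among genes well above background on all 18 arrays, and 270 and 330 with normexp.

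The change from fibroblast to iLung cell itself differed between sources for 650 genes (limb against dorsal MEF), 854 (MDF against dorsal MEF) and 1058 (MDF against limb MEF). Genes called in 1 source alone and different there from both others numbered 32 higher and 45 lower in dorsal MEF, 22 and 34 in limb MEF, and 52 and 49 in MDF. In dorsal MEF they included the adhesion protein Chl1 (4.41 ± 0.50) and, falling, Pitx1, a transcription factor of the hindlimb (-5.11 ± 0.45). In limb MEF they included the myeloid lectins Clec4d (4.24 ± 0.62) and Clec4n (3.96 ± 0.60), and, falling, the muscle caveolin Cav3 (-3.71 ± 0.46). In MDF they included the glutathione transferase Gsta1 (7.42 ± 0.74), the claudin Cldn3 (4.61 ± 0.61) and, falling, the eosinophil chemokine Ccl11 (-4.40 ± 0.55). The 650 became 386 without dorsal MEF replicate 3, 409 without dorsal MEF replicate 2 and 418 without replicate 2 of the iLung cells from dorsal MEF. The 854 became 523, 544 and 538 without dorsal MEF replicates 2 and 3 and MDF replicate 2. With the slide as a block the 650 and 854 were 1092 and 1465, and with normexp the 3 counts were 40, 160 and 288.

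Comparing the fibroblasts with one another shows how the sources differed at the start. Against dorsal MEF, limb MEF (n = 3 and 3) had higher Penk, which encodes enkephalin (10.17 ± 0.51), Thbs4 (7.71 ± 1.18), Comp (7.27 ± 0.66), Plin4 (6.85 ± 0.41), Cav3 (6.40 ± 0.46) and the limb bud factor Lhx2 (6.37 ± 0.58). They had lower Plac8 (-5.64 ± 0.89), Hoxb7 (-5.58 ± 0.97), Hoxb6 (-5.43 ± 0.55), Ifi27l2b (-5.08 ± 0.86), Hoxb3 (-5.02 ± 0.51) and Heyl (-4.94 ± 0.82). Of 21 limb patterning and posterior Hox genes, 14 were higher in limb MEF and 2 lower (median 2.78, adjusted p = 0.000471 with an estimated correlation), and of 20 trunk Hox genes, 12 were lower and none higher (median -2.70, adjusted p = 0.0215 with an estimated correlation). MDF had higher Saa3 (7.55 ± 1.12), Serpina3n (7.41 ± 0.55), Chl1 (7.06 ± 0.50), Prl2c3 (7.03 ± 0.88), Prl2c5 (6.89 ± 0.80) and Rgs8 (6.21 ± 0.82) than dorsal MEF. They had lower Hoxc9 (-6.14 ± 0.88), Slc38a4 (-5.35 ± 0.65), Tnfrsf11a (-4.72 ± 0.60), the scavenger receptor Msr1 (-4.59 ± 0.81), Hoxa7 (-4.55 ± 0.37) and Tbx1 (-4.47 ± 0.58). Rgs8 was not called with normexp (2.80), and Slc38a4 (-0.47) and Tnfrsf11a (-0.46) were not called among genes well above background on all 18 arrays. In all, 2620 genes differed between limb and dorsal MEF, 3357 between MDF and dorsal MEF, and 2121 between MDF and limb MEF. The 2620 became 1708 without dorsal MEF replicate 3, and the 3357 became 1895, 2086 and 2236 without dorsal MEF replicate 3, dorsal MEF replicate 2 and MDF replicate 2. With normexp the 3 counts were 691, 587 and 644, and with the slide as a random block the 3357 became 1885. Of the genes called between MDF and dorsal MEF, 66.9% were higher in MDF (50.2% of those called with quantile normalization). The median difference of all genes was 0.12.

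The iLung cells also differed by source. Those from limb MEF (n = 3 and 3) had higher Pitx1 (6.55 ± 0.45), the cartilage proteoglycan Epyc (6.32 ± 0.90) and Hoxa11 (6.06 ± 0.53) than those from dorsal MEF. Lower in them were Zic1, a transcription factor of the dorsal trunk (-5.18 ± 0.37), Rmnd1 (-5.12 ± 0.19) and the macrophage protein Cd5l (-5.09 ± 0.80, not called when only these groups were fitted). Limb patterning and posterior Hox genes were still higher in them, 11 of 21 higher and 1 lower (median 2.58, adjusted p = 0.000781 with an estimated correlation), whereas the trunk Hox list no longer passed (2 higher and 4 lower, median -1.20, adjusted p = 0.231 with an estimated correlation). Its change between fibroblast and iLung cell was larger in limb than in dorsal MEF by a median of 1.96 (adjusted p = 0.0318 with an estimated correlation). Chondrocyte genes were higher in limb-derived than in dorsal-derived iLung cells, 9 of 12 (median 3.91, adjusted p = 0.00366 with an estimated correlation). iLung cells from MDF had higher Tff1 (7.81 ± 0.96), Retnlb, a secreted protein of goblet cells (7.18 ± 0.50), and the complement factor Cfi (6.69 ± 0.96) than those from dorsal MEF. Lower in them were Cd5l (-9.80 ± 0.80), Tyrobp (-9.25 ± 0.79) and the protease Ctss (-8.90 ± 0.83), which are genes of macrophages. Macrophage genes were lower in iLung cells from MDF than in those from dorsal MEF in 13 of 14 (median -5.80) and than in those from limb MEF in 12 of 14 (median -5.25), each with adjusted p = 0.00344 with an estimated correlation. Mesothelial genes were lower in iLung cells from MDF than from dorsal MEF in 6 of 7 (median -3.21, adjusted p = 0.00767 with an estimated correlation), and club cell genes higher than in those from limb MEF in 9 of 13 (median 2.55, adjusted p = 0.0406 with an estimated correlation). These list tests between sources were added after the data had been seen. In all, 779 genes differed between iLung cells from limb and dorsal MEF, 2618 between those from MDF and dorsal MEF, and 1405 between those from MDF and limb MEF. The 779 became 316 and 1850 without replicates 2 and 1 of the iLung cells from dorsal MEF and 448 and 473 without replicates 2 and 3 of those from limb MEF. The 2618 became 1718 without replicate 3 of those from MDF, and the 1405 became 903 without replicate 2 of those from limb MEF. With the slide as a random block the 3 counts were 289, 1560 and 792, and with normexp 39, 495 and 394. Of the genes called, 80.4% were higher in iLung cells from limb than from dorsal MEF (64.4% of those called with quantile normalization), and 74.0% in those from MDF than from dorsal MEF (51.4%).

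**Figure D4:**
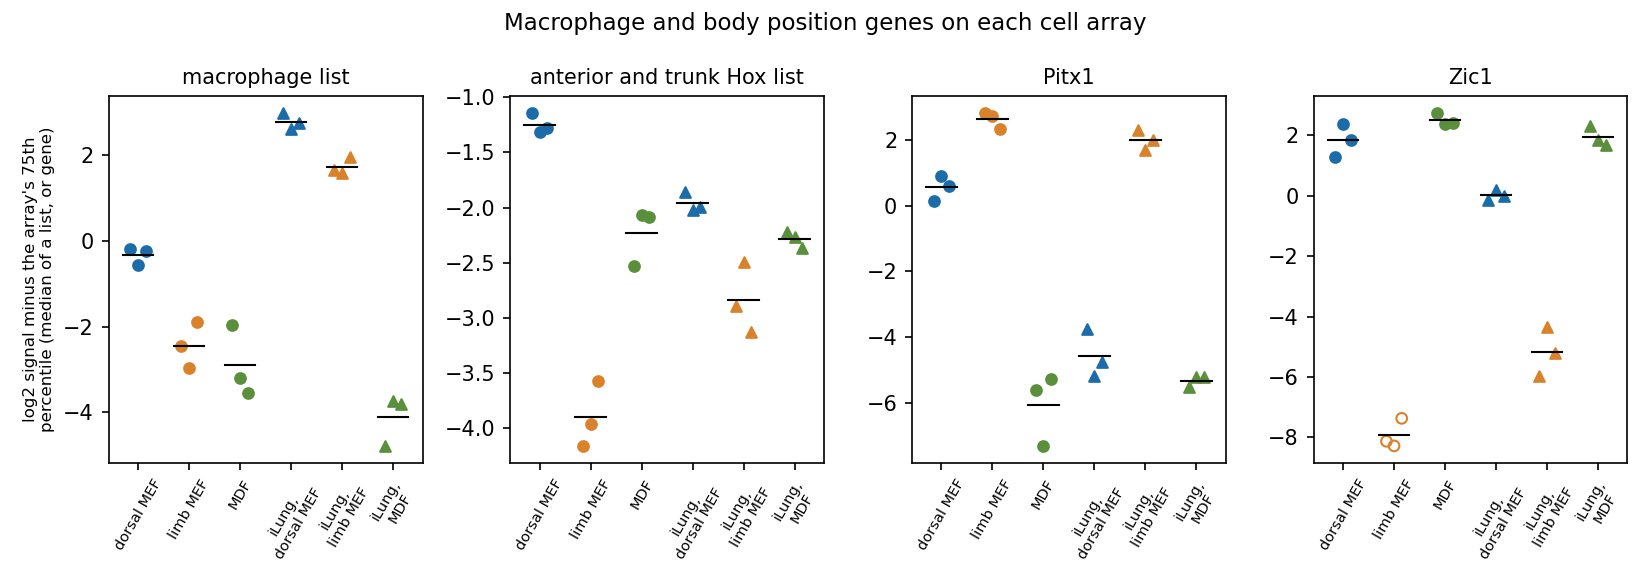
Median log2 signal per array (y axis, minus the array's 75th percentile) of the macrophage list and the anterior and trunk Hox list, and signal of Pitx1 and Zic1, by group on the x axis, with circles for fibroblasts, triangles for iLung cells, points in replicate order and a bar for the mean of 3. The macrophage list lies at 2.60 to 2.98 and 1.59 to 1.96 in iLung cells from dorsal and limb MEF, and at -4.78 to -3.73 in those from MDF.

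The tissue arrays give the levels of the organs the iLung cells are named after or that share their origin. The genes named for each tissue are those with the highest ratio to the next tissue, picked on its 1 array. Any sample would yield such genes, so they do not test which tissue it held. The E11.5 lung had the embryonic globins Hba-x (at least 3037-fold above the next tissue), Hbb-bh1 (at least 2739-fold) and Hbb-y (2209-fold), and the RNA-binding protein Igf2bp3 (at least 120.5-fold). The adult lung had Mlc1 (at least 451.2-fold), the complement component Hc (318.6-fold), Fabp1 (161.2-fold) and Tshb (at least 70.6-fold). The trachea had Reg3g (2505-fold), Bpifb1 (895.2-fold), A2ml1 (732.9-fold) and Muc5b (463-fold). The esophagus had the cornified envelope genes Sprr3 (at least 34270-fold), Lce3f (34290-fold) and Lce1d (at least 26230-fold) and Calm4 (35470-fold), and the thyroid sample had the parathyroid hormone gene Pth (at least 10790-fold), Tg (2852-fold) and Spink8 (at least 315.6-fold). In iLung cells, averaged over the sources, Reg3g (5.92 ± 0.46), Muc5b (3.63 ± 0.48) and Fabp1 (2.48) rose, and Tg (-1.68), Spink8 (-1.31) and Lce3f (-1.27) fell. Of the others measured, Hbb-bh1 (0.47), Hbb-y (-0.17), Igf2bp3 (0.77), Hc (0.50) and Bpifb1 (0.32) did not pass. Sftpc stood at 9.07 in the adult lung (log2 signal minus the array's 75th percentile) and 2.06 in the E11.5 lung, and its mean was -0.33, -0.65 and 4.45 in the iLung cells from dorsal MEF, limb MEF and MDF. Nkx2-1 stood at 1.68 in the adult lung, 2.72 in the thyroid and -0.89 in the E11.5 lung, against -1.75, -2.87 and -1.0 in the 3 groups of iLung cells.

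Of 290 measured genes at least 4-fold higher in the adult lung than in each of the 4 other tissues, 115 rose and 45 fell in the averaged comparison (median 0.63, camera adjusted p = 2.09e-05, and adjusted p = 0.345 with an estimated correlation). Of 414 genes higher in the adult lung than in the 3 other adult tissues, 145 rose and 80 fell (camera adjusted p = 0.00250, and adjusted p = 0.372 with an estimated correlation). Of 2562 genes higher in adult than in E11.5 lung, 762 rose and 396 fell (camera adjusted p = 0.00354, and adjusted p = 0.851 with an estimated correlation), and of 3587 higher in E11.5 than in adult lung, 432 rose and 1195 fell (camera adjusted p = 0.125). Against MDF none of these 3 adult lung lists passed: 68 rose and 48 fell (median 0.12, camera adjusted p = 0.130), 97 rose and 82 fell (0.06, camera adjusted p = 0.330), and 531 rose and 473 fell (-0.08, camera adjusted p = 0.322). Against dorsal and limb MEF, where macrophage genes rose too, the medians of the first list were 0.60 and 0.63. Of 414 trachea genes, 104 rose and 56 fell (camera adjusted p = 0.0177, and adjusted p = 0.851 with an estimated correlation). The lists of the E11.5 lung over the 4 others (1380 genes, 192 rose and 422 fell, camera adjusted p = 0.694), of the esophagus (918 genes, 162 rose and 123 fell, median -0.05 although the test pointed upward, camera adjusted p = 0.399) and of the thyroid (289 genes, 61 rose and 53 fell, camera adjusted p = 0.355) did not pass. Genes of the adult lung list were well above background on all 3 arrays for 57.6%, 61.2% and 59.1% of 389 genes in iLung cells from dorsal MEF, limb MEF and MDF, and for 55.3%, 51.9% and 45.8% in the fibroblasts. The lists were chosen on 1 array per tissue of this series, so their counts are not independent evidence of what marks a tissue, and the E11.5 list over the 4 others turned to a median of 0.22 among genes well above background on all 18 arrays.

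Across 29055 genes, iLung arrays were more similar to the adult lung than fibroblast arrays were (mean Spearman's rho 0.871 ± 0.011 against 0.852 ± 0.006, SD, n = 9 and 9; adjusted p = 0.00125, exact permutation test within source). The difference was 0.0246 and 0.0173 on the 2 scan days, and 0.0255, 0.0223 and 0.0113 in dorsal MEF, limb MEF and MDF, of which the first 2 are the sources whose macrophage genes rose. The correlation with the trachea was higher by 0.0191 (0.0247 and 0.0163 by scan day; exact permutation, adjusted p = 0.00125) and with the esophagus by 0.0160 (0.0170 and 0.0155; exact permutation, adjusted p = 0.00125), each in all 3 sources. With the thyroid it was higher by 0.0065 (0.0121 and 0.0038; exact permutation, adjusted p = 0.0222), though not in MDF (-0.0008), and it did not pass without replicate 1 of the iLung cells from MDF (0.0051). With the E11.5 lung it was lower in all 3 sources, with a difference of -0.0168 (-0.0135 and -0.0185; exact permutation, adjusted p = 0.0122). Among genes well above background on all 23 arrays this last difference turned to 0.0169 (14922 genes; exact permutation, adjusted p = 0.0135). Over the 2000 most variable genes the differences were larger, at 0.138 (adult lung), 0.126 (trachea), 0.0739 (thyroid), 0.0453 (esophagus) and -0.0283 (E11.5 lung). The adult lung and the trachea, as single arrays, correlated at 0.931, and the adult and the E11.5 lung at 0.836. These are pairs on the same slide. The thyroid, on another slide, correlated at 0.909 with the adult lung and 0.834 with the E11.5 lung, so the lungs of different age were no more alike than lung and thyroid.

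**Figure D5:**
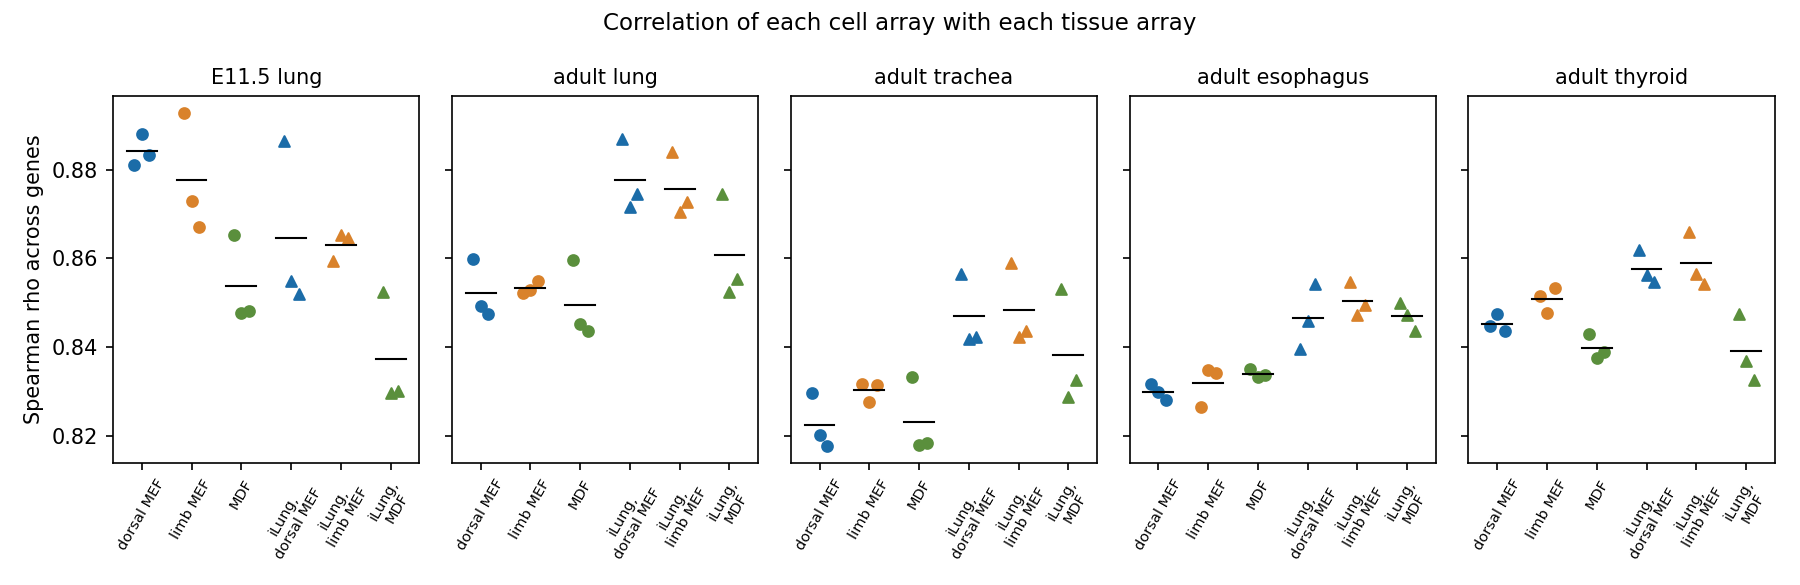
Spearman's rho across 29055 genes between each of the 18 cell arrays and each of the 5 tissue arrays (y axis, which does not start at 0), by group and tissue, with circles for fibroblasts, triangles for iLung cells and a colour per source. Means with the adult lung are 0.850 to 0.853 in the fibroblast groups and 0.861 to 0.878 in the iLung groups.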

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

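The tests of the slide for the macrophage genes, every test of the trunk Hox genes, every count of other splits and the tests of gene lists between sources were chosen after the results had been seen, and the genes of the second macrophage list were chosen before their own values were. What picked out each result below was a difference between groups, that is, a change from fibroblast to iLung cell that differed between sources in a test of the difference itself. Groups of 3 arrays are too small for the test of a sample that lies far from the others, so no array was examined in that way.

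The change differed between sources for 650 genes (limb against dorsal MEF), 854 (MDF against dorsal MEF) and 1058 (MDF against limb MEF). When the 12 arrays of 2 sources were split in other ways, 11, 9 and 4 of 100 drawn splits, the real split included, called as many genes, with up to 3051, 2438 and 1190 in the other splits. Only the third count thereby had a share under 0.05. Differences between the sources enter the other splits, however, so this form of the test cannot decide on chance for any of the 3 counts. Splits that call several times the real count point to a structure of the samples, here the differences between the sources. With these differences taken off before splitting, a form of the test chosen after the first had been seen, only the real split of 100 reached each count (1 in each case, with at most 264, 50 and 8 genes in the others). In that form a chance arrangement of these arrays was argued against, whereas chance between cultures was not tested. Both forms take no account of the slide, and with the slide as a block the 3 counts were 1092, 1465 and 1450.

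Among gene lists, the change in MDF was below that in dorsal MEF for macrophage genes (median difference -3.606, adjusted p = 0.0116 with an estimated correlation). Compared with limb MEF, the change in MDF was lower for macrophage genes (-5.258, adjusted p = 0.00344 with an estimated correlation) and mesothelial genes (-4.408, adjusted p = 0.0318 with an estimated correlation, the value of Upk3b, which was well above background on no limb MEF or MDF array), and higher for limb patterning and posterior Hox genes (0.724, adjusted p = 0.0318 with an estimated correlation), of which Hoxa11 and Hoxd13 were well above background on no MDF array and no iLung array from MDF and so had no room to fall there. The change in anterior and trunk Hox genes was larger in limb than in dorsal MEF (1.959, adjusted p = 0.0318 with an estimated correlation).

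Macrophage genes rose in iLung cells from dorsal and limb MEF and not, as a list, in those from MDF. A shift shared by all arrays of a slide cancels between its iLung and fibroblast arrays, so by the layout it could not make this rise. The list's median change within each of the 4 slides of dorsal and limb MEF, at least 2.915, restates the rise and is no separate test. An effect of a slide on its iLung arrays alone was not tested. Macrophages among the cells of the MEF-derived cultures are a candidate explanation, for which the labels name no sort or gate that would remove them: of 12 further abundant macrophage transcripts, 11 were tested, and 11 of 11 rose in the comparison with limb MEF and 11 of 11 in that with dorsal MEF (medians 4.647 and 3.262). In MDF 1 of them rose, Lcp1 (3.50), and 3 fell (median -0.559). Tyrobp, an abundant transcript of these cells, stood at 4.31 and 4.07 in iLung cells from dorsal and limb MEF, against 1.30 and -1.81 in the fibroblasts, and at -4.95 in those from MDF, against -4.27, and a difference between embryonic and adult sources in the cells themselves stays open and was not tested.

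Anterior and trunk Hox genes rose in iLung cells from limb MEF, 7 of 20, among them Hoxb2 (2.73) and Hoxb6 (2.69), although 3 of the 7, Hoxc5, Hoxc8 and Hoxc9, did not pass the test of a difference from their change in dorsal MEF (adjusted p = 0.562, 0.592 and 0.312). A single array as the cause was argued against (camera adjusted p at most 0.00965 without any of the 6 arrays, although with all 6 arrays adjusted p = 0.191 with an estimated correlation). A shift shared by all arrays of a slide cancels here too by the layout, and the median change of at least 1.139 within each of the 2 slides restates the rise. An effect of a slide on its iLung arrays alone was not tested. An even admixture of iLung cultures from dorsal MEF was also argued against, though only by 2 genes picked on the ratio that was then tested. The 7 called Hox genes would need a median share of 35.3% of the level in iLung cells from dorsal MEF, from 12.5% (Hoxc8) to 42.8% (Hoxc5). Zic1 and Rmnd1, high in both dorsal groups, reached at most 4.84% on any array. These 2 genes were picked after their values had been seen, having been named above for the largest falls between the same groups of iLung cells. Other cells of dorsal origin may still be the source, and a count of genes did not decide it. Of 26 genes lower in limb than in dorsal MEF and bright in iLung cells from dorsal MEF, 2, Zic1 (2.75%) and Rmnd1 (2.87%), stayed under 25% of that median share on all 3 arrays. At least 3 would have argued against it, a bound set after results had been seen, and Fggy (4.16%, at most 10.4% on an array) lay near the cut. The 26 include genes that macrophages (Aif1, Marco) or mesothelium (Wt1, Upk1b, Bnc1) express. Some stood above the level in iLung cells from dorsal MEF, such as Upk1b (138%) and Ms4a7 (128%), and so cannot report on dorsal cells. Exchanged labels were not seen, as all 6 iLung arrays from dorsal and limb MEF correlated with the side of their own source across 2620 genes (r 0.394 to 0.479, and -0.502 to -0.439), and a change in the limb cells' own Hox genes stays open and was not tested.

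Genes called in 1 source alone, with a change that differed from both other sources, are given with their log2 change (n = 3 and 3). In dorsal MEF, Chl1 (4.407), Hs3st1, which modifies heparan sulfate (4.276), and Amph, a protein of endocytosis (4.264), rose, and Lingo2 (-5.530), Pitx1 (-5.109) and the matrix protein gene Sparcl1 (-3.487) fell. In limb MEF, Clec4d (4.236), the surface protein gene Cd200 (4.203) and Clec4n (3.961) rose, and Cav3 (-3.713), the receptor gene Adgrg2 (-3.142) and Wdr72 (-2.966) fell. In MDF, Gsta1 (7.417), Lypd6 (6.132) and Cldn3 (4.608) rose, and Ccl11 (-4.399), the xanthine dehydrogenase gene Xdh (-4.032) and Gpnmb (-3.662) fell. The calls of Amph (1.95), Sparcl1 (-2.13) and Wdr72 (-1.83) were lost with normexp, and Lypd6 turned to -0.077 with the filter on all 18 arrays, where another probe stood for the gene.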

How the results depend on the processing

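The second scan day alone, the scan day as a block and the slide as a random block were chosen after the data had been seen, and all other alternatives before. Of the named genes called, each counted with its comparison, 170 of 213 were the same under every alternative that tested them. Not every alternative tested all of them. The filter on all 18 arrays left out the genes dim on some arrays, with 119 the same, 2 weaker and 1 reversed. The slide and the replicate number as a block left out comparisons among fibroblasts and among iLung cells. Over all alternatives and left-out arrays, counts of genes or lists were within 1.5 times in 605 cases and moved further in 78. Named genes kept direction and side of the threshold in 6647 cases, were weaker in 67 (36 of them with normexp) and reversed in 1. Fixed lists were the same in 4525 cases, weaker in 112 and stronger in 91, and tissue lists the same in 1012, weaker in 56, stronger in 17 and reversed in 3. Of the 6147 calls of the averaged comparison, 5882 were kept with quantile normalization, 5899 with the mean of a gene's probes, 6145 with the deposited table and 2713 with normexp. Quantile normalization moved the median of all genes by over 0.1 in 4 comparisons: MDF against dorsal MEF (0.123 to 0.000), iLung cells from MDF (0.165 to 0.035) and from limb MEF (0.135 to 0.035) against those from dorsal MEF, and iLung cells against dorsal MEF (-0.186 to -0.073). How far signal near background limits the counts was not tested apart from the filter on all 18 arrays and normexp, whose counts follow.

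With the filter on all 18 arrays, where fewer genes are tested, the counts higher and lower were 1218 and 1719 (averaged), 453 and 852 (all 3 sources), 1299 and 1901 (dorsal MEF), 1260 and 1582 (limb MEF) and 1388 and 2002 (MDF). In the order limb against dorsal MEF, MDF against dorsal MEF and MDF against limb MEF, kept below, that filter gave 409, 1137 and 741 between iLung cells and 1703, 2091 and 1336 between fibroblasts, and 653 for the last difference of changes. With normexp the counts higher and lower were 1184 and 1549 (averaged), 270 and 330 (all 3 sources), 760 and 796 (dorsal MEF), 943 and 968 (limb MEF) and about 1.1e+03 and 1388 (MDF). It gave 39, 495 and 394 between iLung cells, 691, 587 and 644 between fibroblasts, and 40, 160 and 288 for the differences of changes; the cause was not tested. With no minimum fold, 5150 genes were higher and 7337 lower in the averaged comparison. A fit of only the groups compared gave 128 (limb against dorsal) and 740 (MDF against limb) between iLung cells. The second scan day alone, with 2 arrays per group, gave 3575, 4765 and 2864 between iLung cells, 4810 and 5704 for the first 2 pairs of fibroblasts, and 3000, 2289 and 1951 for the differences of changes. On that day both arrays of a group shared a slide, and each source had its own, so the spread held only differences within a slide. Replicates differed by an SD (log2) of 0.464 to 0.719 on the same slide and 0.760 to 1.008 across slides. These higher counts are therefore no stronger evidence of a difference between sources. The slide as a random block (consensus correlation 0.369) gave 289, 1560 and 792 between iLung cells, 1885 for MDF against dorsal MEF, and 1232 and 1549 for the first 2 differences of changes, which were 1092 and 1465 with the slide as a fixed block.

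Of 148 list tests, 60 passed with the preset correlation, 0 with camera's estimated correlation (38 at an unadjusted p under 0.05) and 98 with fry. Of 32 tests of tissue lists, 13 passed, against 0 with the estimated correlation (4 unadjusted), 5 with the filter on all 18 arrays, 4 with normexp and 4 with lists at 2-fold. Similarity to the E11.5 lung reversed to 0.0169 among genes well above background on all 23 arrays. With the filter on all 18 arrays the list of adult over E11.5 lung turned to -0.136 (limb MEF), that of the E11.5 lung over the 4 others to 0.280 (limb MEF) and 0.222 (averaged), and Lypd6 to -0.077 (MDF), where another probe stood for the gene. The cause of the other reversals was not tested.

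Leaving out 1 array in turn gave 1895 to 4339 genes between MDF and dorsal MEF (1895 without dorsal MEF replicate 3, 2086 without its replicate 2, 2236 without MDF replicate 2) and 1708 to 3172 between limb and dorsal MEF (1708 without dorsal MEF replicate 3). Between iLung cells it gave 316 to 1850 for limb against dorsal MEF (316 and 1850 without replicates 2 and 1 from dorsal MEF, 448 and 473 without replicates 2 and 3 from limb MEF), 1718 to 3067 for MDF against dorsal MEF (1718 without replicate 3 from MDF) and 903 to 1822 for MDF against limb MEF (903 without replicate 2 from limb MEF). For the differences of changes it gave 386 to 841 for limb against dorsal MEF (409 and 386 without dorsal MEF replicates 2 and 3, 418 without replicate 2 of their iLung cells) and 523 to 1086 for MDF against dorsal MEF (523 and 544 without dorsal MEF replicates 2 and 3, 538 without MDF replicate 2). Similarity to the thyroid ran from 0.0051 to 0.0076 and did not pass without replicate 1 of the iLung cells from MDF.

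With the replicate number as a block, all 15 counts were within 1.5 times (2492 higher and 3655 lower in the averaged comparison), 59 list tests passed, and 1 gene and 2 lists were weaker and 1 list stronger. Whether the numbers pair the samples could not be settled. Deviations from the group means correlated between fibroblast and iLung replicates of the same number at 0.258, 0.226 and -0.017 (dorsal MEF), 0.217, 0.124 and 0.057 (limb MEF) and 0.316, 0.183 and -0.026 (MDF), and dorsal MEF replicate 3 correlated better with iLung replicate 2 (0.264). With 3 arrays per group, and replicate 1 on another slide and scan day than the others, these correlations also carry the slide.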

Other observations

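The list of differentiated epidermis genes, the counts of other splits and the tests of gene lists between sources were chosen after other results had been seen, and the 3 tests on genes without a symbol were chosen before their own results. In iLung cells from limb MEF the cartilage genes Cnmd (7.09 ± 0.74, on 3 iLung arrays and 1 limb MEF array) and Col9a3 (5.05 ± 0.48) rose, and in those from MDF Comp (5.89 ± 0.66) and Col9a3 (3.13 ± 0.48) rose and Cnmd was at least 5.93-fold higher. Against dorsal MEF, 5 of 12 chondrocyte genes rose and 1 fell (camera adjusted p = 0.0544), Col9a3 (-0.01) did not pass, and Cnmd was well above background on none of the 6 arrays. Of 11 adipocyte genes, 6 rose against dorsal MEF (camera adjusted p = 0.00081, and adjusted p = 0.0629 with an estimated correlation). Against MDF 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00536, and adjusted p = 0.0842 with an estimated correlation), with the complement factor Cfd at least 19.6-fold and the adipokine Adipoq at least 9.99-fold higher. Against limb MEF 3 rose and 1 fell (camera adjusted p = 0.254), with Cd36 (5.78 ± 0.72). The change of this list differed between limb and dorsal MEF by a median of -0.60 (camera adjusted p = 0.0226, and adjusted p = 0.199 with an estimated correlation).

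Fibroblast sources also differed in cell cycle genes, of which 21 of 24 were lower in MDF than in dorsal MEF and none higher (median -1.66; camera adjusted p = 2.52e-13, and adjusted p = 0.279 with an estimated correlation). In limb MEF 9 of 24 were lower than in dorsal MEF (median -1.16; camera adjusted p = 2.84e-08, and adjusted p = 0.430 with an estimated correlation). Of 9 listed genes of differentiated epidermis 6 were tested, and in the averaged comparison 3 rose and 1 fell. Ly6d (6.94, 6.09 and 8.74) and Dmkn (3.82, 4.59 and 5.65), which mark stratified epithelium, rose against dorsal MEF, limb MEF and MDF, and the protease inhibitor Cst6 fell against dorsal and limb MEF (-2.06 and -1.72).

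Genes called lower in iLung cells were more often without a symbol than genes called higher: of 7016 genes without a symbol 30.87% were called lower, against 9.45% of genes with a symbol. Dim signal as the cause was argued against, since of genes with a symbol matched on mean signal 9.76% were called lower. Scaling between arrays was argued against as well, with 61.08% of lower and 20.45% of higher calls without a symbol under quantile normalization, a ratio of 2.99. Scan day was too, as the median change of genes without a symbol lay below that of genes with one on both days (-0.341 and -0.379). No biological explanation was tested.

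Other splits of the arrays were counted for each comparison. In the averaged comparison, 1 of 100 drawn splits, the real split, reached its 6147 genes (at most 4200 in the others). A chance arrangement of these arrays was thereby argued against. Chance between cultures was not tested, since the samples of a group may not be separate cultures. For the 2612 genes shared by all 3 sources, 1 of 100 also reached the count (at most 0 in the others). Mixed splits within 1 source called at most 84 genes, so they left little to share, and this second count adds little. With 3 arrays against 3, the 10 splits are too few for a share under 0.05. Of these, only the real split (1) reached its count for iLung cells against dorsal MEF (5774, at most 0 in the others), limb MEF (5148, at most 1) and MDF (5810, at most 84). The same held between fibroblasts for limb against dorsal MEF (2620, at most 146), MDF against dorsal MEF (3357, at most 0) and MDF against limb MEF (2121, at most 0), and between iLung cells for MDF against dorsal MEF (2618, at most 137) and MDF against limb MEF (1405, at most 13). Between iLung cells from limb and dorsal MEF, 2 of 10 splits reached the real 779, and the other, which exchanged the replicates 1, both scanned on the first day, called 1011. On the second scan day alone this comparison gave 3575, but there the arrays of a group share a slide, and source and slide cannot be told apart.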
